A study of Daphnia magna with 60 samples.

How the data were processed

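Gene expression was measured in whole adult females of the water flea Daphnia magna, a freshwater crustacean used in toxicity testing. The animals were 10 days old and were exposed for 24 h to silver nitrate (AgNO3), which releases silver ions, to citrate-coated silver nanoparticles or to silver nanoparticles coated with polyvinylpyrrolidone (PVP). Each of the 60 arrays measured RNA pooled from 5 animals of a separate replicate exposure, per the labels and the series' design text. The labels place the arrays in 3 exposures, each with its own unexposed control group, and in 10 groups of 6 arrays. P-values therefore measure the spread between separate pools.

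Labelled RNA was hybridised to a one-colour Agilent array, and the scans were quantified by the authors with Agilent Feature Extraction 9.5.1, per the submitters' processing notes. Per the file headers, the deposited scanner files give for each spot a processed signal intensity that the software had background-subtracted and detrended within the array, together with mean and median pixel intensities and quality flags. The deposited value table of the whole series held the unscaled median pixel intensity of the same spots: on every array the greatest difference from the scanner file was 0. Its column medians ranged from 95 to 215.5, so it had not been centred. It was linear in scale, and since each array carried 1 colour its values have no direction.

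The array held 15208 non-control spots of 14338 probes, of which 870 had 2 spots. There were 12648 probes of 50 bases and 1690 of 60 bases. All 14338 probes were described as unknown and listed as unmapped in the files, and none of their identifiers was found in a reference table of 28335 D. magna genes. The files do not pair the probes with gene names, so probes are given by identifier, no genomic position can be stated, and none of the 32 gene lists fixed before the data were examined matched a probe. The files also do not establish that every probe targets a D. magna transcript. The planned gene list tests were not run.

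Values were log2 ratios of the processed signal to its 75th percentile over the non-control spots of the array, with a floor at 0.01 of that percentile set after scaling. Spots carrying the software's non-uniformity or population outlier flags were left out, and spots of 1 probe were averaged. A probe was tested where it was well above background on at least 4 of the 6 arrays of at least 1 group in the fit and where at least 0.5 of each group's arrays had a value. The requirement on missing values was set after the first counts had been seen. The first runs allowed at most 6 missing arrays per probe, and 12 probes then differed between the effects of PVP 8.1 and AgNO3 0.32. The rule was changed so that subsets of slides could be fitted, and the count became 3, with 12 probes under an adjusted p of 0.051. Both counts are given. Arrays give no counts, so the number of arrays limits the precision. The 75th percentile of the processed signal ranged from 305 to 859 per array, and 9570 to 13736 spots per array were well above background.

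Tests were made with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each exposure was fitted alone, with its groups sharing 1 estimate of the spread. Differences between 2 effects from different exposures and the moderated F test over the 3 control groups used 1 fit of all 60 arrays. The design was fixed before the data were examined. The rule for named probes, fixed at the same time, asked for named genes past the threshold; with no table of names it allowed at most 2 probes that rose and 2 that fell. How many were given within that limit was settled later. For each comparison with control, the 2 probes with the lowest p in each direction are given, and for the other comparisons 1 in each direction together with any further probe past the threshold where fewer than 5 passed. Probes outside this rule are said to be so where they appear. Named probes were chosen by lowest p on the same arrays, so agreement of single arrays in direction adds no separate support.

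The steps were tested on simulated data, in which 200 probes were changed by 2-fold or 4-fold, and the same changes were then added to the real arrays. In AgNO3 0.32 against control, over 10410 probes, 31 of 100 added 2-fold changes and 80 of 100 added 4-fold changes were called. In citrate 0.43 against control, over 11587 probes, these counts were 65 and 96, and in PVP 8.1 against control, over 11748 probes, they were 61 and 91. Among the probes left as measured, 16, 0 and 79 were called as well in these 3 comparisons; in data simulated without other differences these counts were 4, 8 and 12.

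Slide and scan day were read from the files. The AgNO3 exposure lay on slides 5, 6 and 8, each with 2 arrays of each of its 4 groups, and was scanned on a different day from the nanoparticle exposures, which shared slides 1, 2, 3, 4 and 7. Slide 3 was quantified with version 5 of the extraction protocol and the other slides with version 1. AgNO3 and nanoparticle exposures therefore cannot be separated from slide and scan day. The nanoparticle groups were not spread evenly over their slides, and the main fits had no slide term. Slide 7 held no array of the low-dose control or of citrate 0.43. Slide 3 held 2 arrays each of PVP 8.1 and citrate 3.5 but 1 of their control. Arrays of slide 3 had at least 13149 spots well above background, and all others at most 12828.

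Correlations of fold changes were set against 1000 simulations of unchanged groups, made by shuffling arrays within slides. Free shuffles were used first and were replaced after their covariances were seen to lie above the observed ones; with both, none of the 21 pairs lay outside the simulated range.

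Alternatives were normexp background correction with an offset of 50 and quantile normalization, median centring, the deposited value table on a log2 scale, no filter, a filter requiring signal on every array, replicate number or slide as a block, array weights, and all 60 arrays in one fit. Alternatives added after the data were examined were removal of each array's spatial trend, single slides, leaving out doubted slides, the first limit on missing values, array scores as covariates, and leaving out single arrays that stood apart. Regroupings of the arrays, at most 100 per comparison, were drawn freely and, added later, within slides.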

Results

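Transcript levels were measured on 60 one-colour arrays of whole D. magna after 24 h of exposure, with 6 arrays per group. In the first exposure, animals were kept unexposed or in AgNO3 at 0.08, 0.16 or 0.32 µg/L. In the second they were kept unexposed or in a low dose of citrate-coated (0.43 µg/L) or PVP-coated (1.0 µg/L) silver nanoparticles, and in the third unexposed or in a high dose of the citrate-coated (3.5 µg/L) or PVP-coated (8.1 µg/L) particles. The comparisons ask how each form of silver changed transcript levels, whether the response depended on dose and coating, and whether particles differed from silver ions. Values are log2 ratios to the array's 75th percentile, given as mean ± SD with n = 6, and adjusted p-values are from limma. Correlations between arrays of one group lay between 0.82 and 0.97 in the AgNO3 exposure and between 0.90 and 0.98 in the nanoparticle exposures. The median SD within a group averaged 0.49 in the AgNO3 exposure, 0.35 in the low-dose and 0.37 in the high-dose nanoparticle exposure.

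The first question was whether AgNO3 changed transcript levels. The lowest p at 0.08 µg/L belonged to probe DM00848P1, at -0.56 ± 0.50 in AgNO3 0.08 and -2.56 ± 0.64 in control, a difference of 1.99 (SE 0.39, 95% interval 1.18 to 2.81, adjusted p = 0.466). It was above the control mean on 6 of 6 arrays. At 0.32 µg/L the same probe stood at -0.89 ± 0.78, 1.67 above control (SE 0.39, adjusted p = 0.292). By inspection its sequence resembles bacterial ribosomal RNA, which was not tested, and the files do not settle which organism its transcript comes from. DM04987P1 was at -0.28 ± 0.83 in AgNO3 0.32 against -1.81 ± 0.43 in control, a difference of 1.53 (SE 0.34, adjusted p = 0.274). The lowest p at this dose belonged to DM10695P1 (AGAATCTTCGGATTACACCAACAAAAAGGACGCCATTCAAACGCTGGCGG), at -2.06 ± 0.25 against -0.95 ± 0.35, a difference of -1.12 (SE 0.20, 95% interval -1.54 to -0.70, adjusted p = 0.168). DM11131P3 (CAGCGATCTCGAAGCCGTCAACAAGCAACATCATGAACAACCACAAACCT) differed by -0.95 (SE 0.19, adjusted p = 0.225). Both were below the control mean on 6 of 6 arrays.

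At 0.16 µg/L, DM00355P1 (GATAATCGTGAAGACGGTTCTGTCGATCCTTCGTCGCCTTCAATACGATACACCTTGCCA) was at -1.05 ± 0.42 against 0.04 ± 0.19 in control, a difference of -1.09 (SE 0.25, 95% interval -1.61 to -0.57). DM04572P2 differed by -0.76 (SE 0.18), DM02605P2 by 0.57 (SE 0.18) and DM01970P1 by 1.46 (SE 0.48). At 0.08 µg/L, DM00259P2 differed by 0.56 (SE 0.17) and DM01266P2 by -0.53 (SE 0.16). DM03056P3 was well above background on 4 of 6 control arrays and on none of the AgNO3 0.08 arrays. By group means control was at least 2.06-fold brighter. For this bound each dim array took the higher of its own signal and the lowest signal well above background. The 95% interval of the measured log2 difference was wider, -1.88 to -0.46. None of these differences passed the adjusted threshold. Of 10410 probes tested, limma called 0 at any of the 3 doses. At an unadjusted p under 0.05 there were 168 probes at 0.08 µg/L, 149 at 0.16 µg/L and 476 at 0.32 µg/L, where 520.5 would arise from uniform p-values. These counts depended on the processing: with the deposited value table they were 39, 40 and 172, and with the replicate block 234, 209 and 604. The 95% interval excluded a 2-fold change in either direction for 61.6%, 63.1% and 58.8% of probes. With all 60 arrays in one fit, which gives the AgNO3 arrays a spread shared with the less variable nanoparticle arrays, the counts were 1, 0 and 21. With slide as a block limma called 0 probes at each dose, with 225 at 0.08 µg/L and 586 at 0.32 µg/L at an unadjusted p under 0.05, and within single slides, with 2 arrays per group, it called 4 probes on slide 5 at 0.08 µg/L.

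Arrays of this exposure also differed by position on the glass. Each array's rows were divided into 10 bands, numbered from its first row, and the median deviation of a band from the probe means of the exposure was averaged over the 4 arrays of a slide column. The pattern was reversed between columns. In the first column of slides 5 and 6, band 1 was at -0.41 and -0.36 and band 10 at 0.20 and 0.28. In the other column, band 1 was at 0.33 and 0.29 and band 10 at -0.42 and -0.29. On slide 8 bands 1 and 10 were both above 0, at 0.13 and 0.27 in the first column and 0.21 and 0.15 in the other. The lowest bands of single arrays on slides 5 and 6 lay between -0.73 and -0.11.

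**Figure D1:**
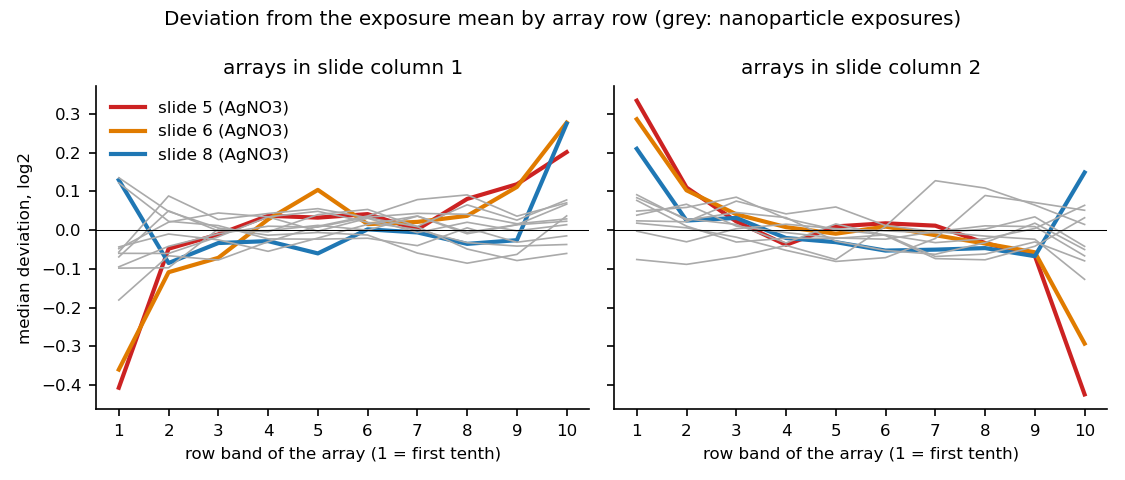
Median deviation of log2 signal from the probe means of the exposure by band of array rows, averaged over the arrays in the first and second column of each slide. On slides 5 and 6, band 1 was dim (-0.41 and -0.36) and band 10 bright (0.20 and 0.28) in the first column, and the reverse held in the other column, while on slide 8 both lay between 0.13 and 0.27.

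**Figure D2:**
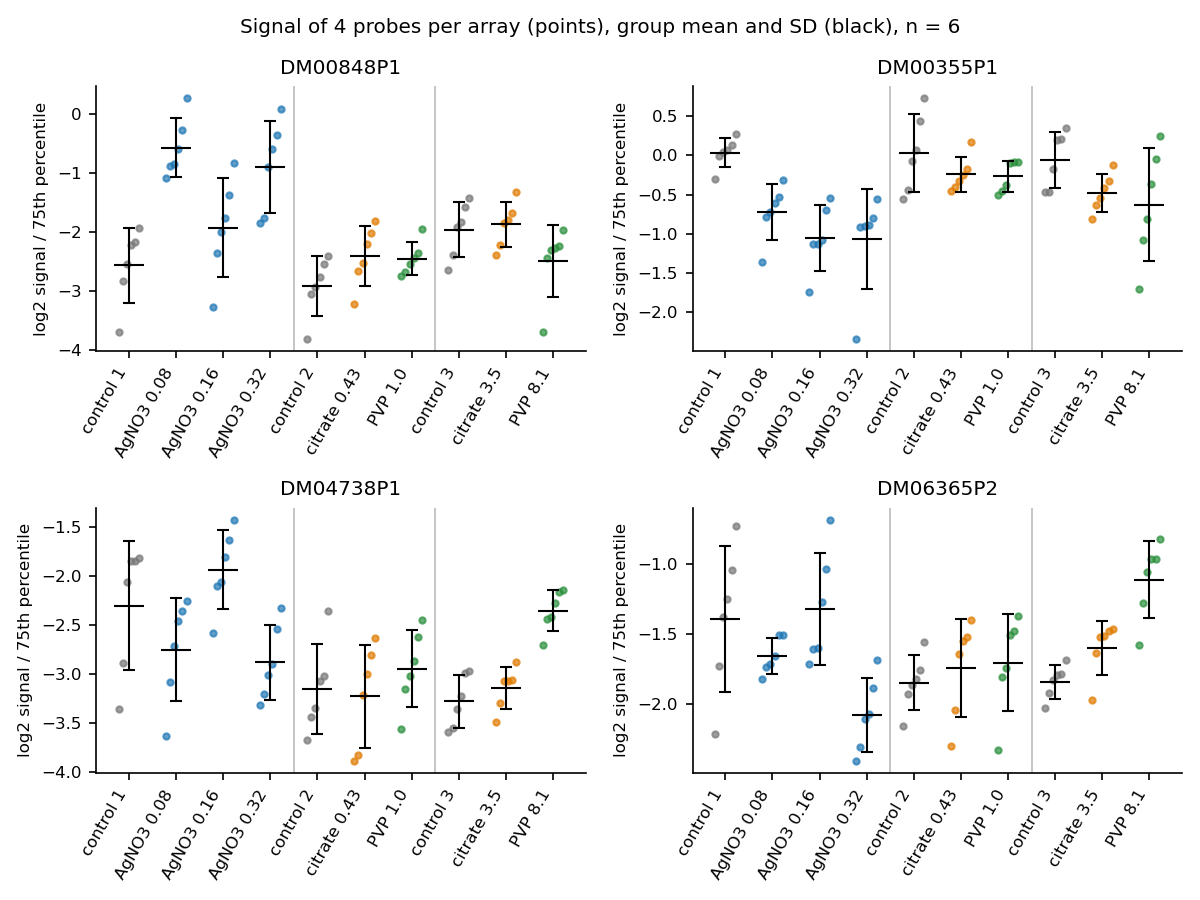
Signal of 4 probes on each array (points; log2 of signal over the array's 75th percentile) in the 10 groups, with group mean and SD in black and grey lines between exposures. DM00848P1 averaged -2.56 in the AgNO3 control and -0.56 in AgNO3 0.08, DM00355P1 averaged 0.04 and -1.05 in that control and AgNO3 0.16, and DM04738P1 and DM06365P2 stood highest relative to their own control in PVP 8.1.

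The effect of AgNO3 dose was tested by setting 0.32 µg/L against 0.08 µg/L. DM11353P1 was at -2.39 ± 0.47 at the high dose and -1.57 ± 0.23 at the low dose, a difference of -0.82 (SE 0.20). DM09354P1 differed by 1.19 (SE 0.34), and was well above background on 4 of 6 arrays at the high dose and 1 of 6 at the low dose. Neither passed adjustment, and limma called 0 of 10410 probes, with 248 at an unadjusted p under 0.05. The 95% interval had a median half-width of 0.61 and excluded a 2-fold difference for 60.7% of probes.

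In the low-dose nanoparticle exposure, DM09696P2 had the lowest p among higher probes for both coatings. It was at -3.74 ± 0.71 with citrate-coated and -3.45 ± 0.51 with PVP-coated particles against -5.10 ± 0.61 in their shared control, differences of 1.36 (SE 0.33) and 1.65 (SE 0.33, adjusted p = 0.754). It was well above background on 6 of 6 arrays in both exposed groups and on 2 of 6 control arrays. With citrate-coated particles, DM07050P2, well above background on 4 of 6 exposed and 6 of 6 control arrays, differed from control by -1.83 (SE 0.54), DM00986P4 by -0.41 (SE 0.12) and DM09891P1 by 0.51 (SE 0.15). In the order given, these probes stood at -4.50, 0.84 and -3.01 with citrate and at -4.57, 0.83 and -3.11 with PVP. DM07050P2 was at -2.67 in the shared control, far above the AgNO3 control (-5.76) and the high-dose control (-5.11). With PVP-coated particles, DM01970P1 was at 4.52 ± 0.74 against 6.27 ± 0.45, a difference of -1.74 (SE 0.36, adjusted p = 0.754). DM09236P4 differed by -0.37 (SE 0.09) and DM05398P2 by 1.18 (SE 0.26), the latter well above background on 4 of 6 exposed arrays and on 1 of 6 control arrays. Limma called 0 of 11587 probes for either coating, with 194 probes for citrate and 363 for PVP at an unadjusted p under 0.05. With the replicate block these unadjusted counts were 408 and 759, and with the slide block 437 and 495. The 95% interval excluded a 2-fold change for 84.9% and 83.9% of probes.

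In the high-dose nanoparticle exposure, PVP-coated particles gave the lowest p-values of the comparisons with control. DM04738P1 (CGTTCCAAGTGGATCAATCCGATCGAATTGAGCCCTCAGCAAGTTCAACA) was at -2.36 ± 0.21 in PVP 8.1 and -3.28 ± 0.27 in control, a difference of 0.92 (SE 0.15, 95% interval 0.62 to 1.23, adjusted p = 0.0574). DM00990P4 (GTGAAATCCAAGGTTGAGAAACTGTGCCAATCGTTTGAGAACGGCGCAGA) was at -1.83 ± 0.41 against -2.95 ± 0.22, a difference of 1.11 (SE 0.18, adjusted p = 0.0574). DM08402P2 (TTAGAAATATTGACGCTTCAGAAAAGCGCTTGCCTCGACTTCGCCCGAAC) differed by -0.67 (SE 0.12, adjusted p = 0.0635). DM12265P1 (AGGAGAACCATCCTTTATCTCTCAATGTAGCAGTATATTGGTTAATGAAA) was at 3.41 ± 0.57 against 4.68 ± 0.23, a difference of -1.27 (SE 0.24, adjusted p = 0.0684). Each of these 4 probes lay on the same side of the control mean on 6 of 6 exposed arrays, as probes chosen by lowest p tend to. Limma called 0 of 11748 probes, with 989 at an unadjusted p under 0.05 where 587.4 would arise from uniform p-values. That count of 0 depended on the processing: it was 17 with normexp and quantile normalization, 26 without a filter and 15 over probes well above background on every array, and it was 0 with slide as a block, with 1265 at an unadjusted p under 0.05. Without slide 3 limma called 0 and the lowest adjusted p was 0.385, with 816 at an unadjusted p under 0.05.

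With citrate-coated particles at 3.5 µg/L, DM05275P1 differed from control by -0.60 (SE 0.15), DM08948P2 by -0.54 (SE 0.14), DM09390P2 by 0.51 (SE 0.18) and DM00761P3 by 1.03 (SE 0.36). None passed adjustment. DM00761P3 was well above background on 4 of 6 exposed arrays and on 1 of 6 control arrays, and its difference was 0.63 (SE 0.22) without citrate 3.5 replicate 6. DM05275P1 was well above background on 4 of 6 exposed and 5 of 6 control arrays. Limma called 0 of 11748 probes, with 290 at an unadjusted p under 0.05, and the 95% interval excluded a 2-fold change for 83.6% of probes. The unadjusted count was 576 with the replicate block and 401 with the slide block.

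**Figure D3:**
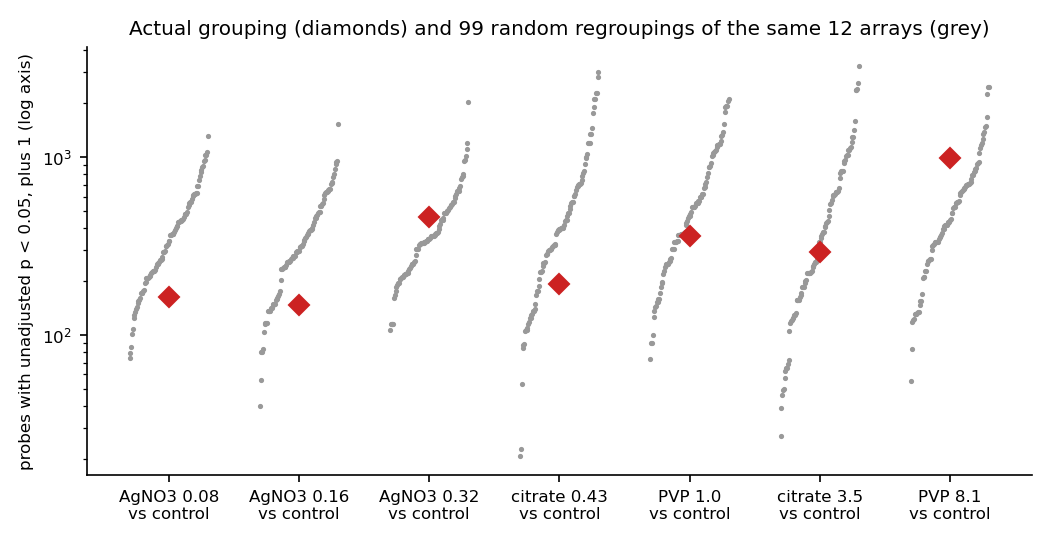
Number of probes at an unadjusted p under 0.05, plus 1, on a log axis, for the actual grouping (red diamonds) and for 99 random regroupings of the same 12 arrays, drawn freely across slides (grey points), in each comparison with control. The actual count for PVP 8.1 was 989, a value reached by 14 of the 100 groupings counting the actual one, and for AgNO3 0.16 it was 147 over probes with no missing spot, reached by 84 of the 100 groupings.

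The 2 coatings were compared directly at each dose step, at nominal doses that differed between coatings and were taken in the design as equally toxic. At the low step, DM10516P2 was 0.81 higher (SE 0.23) and DM01489P3 0.72 lower with citrate than with PVP (difference -0.72, SE 0.23). At the high step, DM00705P1 was at -3.32 ± 0.24 with citrate-coated and -2.50 ± 0.27 with PVP-coated particles, a difference of -0.82 (SE 0.14, 95% interval -1.12 to -0.53, adjusted p = 0.114). DM08402P2 differed by 0.42 (SE 0.12). No probe passed adjustment with limma at either step, with 176 of 11587 and 302 of 11748 probes at an unadjusted p under 0.05. The 95% interval excluded a 2-fold difference between coatings for 84.6% and 83.4% of probes.

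The change of effect with nanoparticle dose was tested as the effect against control at the high dose minus that at the low dose. For PVP, DM04369P3, which varied widely within groups, had an effect of -2.71 at 8.1 µg/L and 3.40 at 1.0 µg/L, a difference of -6.11 (SE 1.31, adjusted p = 0.249). DM13182P1 had effects of 0.78 and -0.44, a difference of 1.22 (SE 0.28, adjusted p = 0.254). It was well above background on 6 of 6 arrays in PVP 8.1, 3 of 6 in its control, 2 of 6 in PVP 1.0 and 5 of 6 in that control. For citrate, DM08285P1 had effects of -0.41 and 0.42 (difference -0.83, SE 0.22) and DM02514P1 effects of 0.17 and -0.51 (difference 0.67, SE 0.31). Limma called 0 of 11951 probes for either coating, with 333 for PVP and 116 for citrate at an unadjusted p under 0.05. With the replicate block, 2 probes passed for PVP, and more passed with array weights.

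Particles were set against silver ions in the same way, dose step by dose step. Between the effects of PVP 8.1 and AgNO3 0.32, 3 of 11951 probes passed, with 436 at an unadjusted p under 0.05. DM06365P2 was 0.73 above its control with PVP 8.1 and stood at -0.69 relative to its own control with AgNO3 0.32, a difference of 1.42 (SE 0.26, 95% interval 0.90 to 1.93, adjusted p = 0.0114). DM04885P2 had effects of 0.72 and -1.09, a difference of 1.81 (SE 0.34, adjusted p = 0.0114), and DM00679P3 effects of 0.68 and -0.54, a difference of 1.22 (SE 0.25, adjusted p = 0.0345). On 6 of 6 PVP 8.1 arrays these 3 probes were above the mean of their control. In the order given, they stood at -1.11, -1.62 and 0.64 in PVP 8.1 and at -1.39, -1.61 and 0.69 in the AgNO3 control. In AgNO3 0.16 they were at -1.32, -1.63 and 0.71, near that control. In AgNO3 0.08 they were lower, at -1.66, -2.21 and 0.24, so the AgNO3 effects did not change steadily with dose. DM00848P1 had effects of -0.52 and 1.67, a difference of -2.19 (SE 0.46), and just missed the threshold. The calls were lost with array weights, with the deposited value table, without slides 5 and 6 and without slide 3, each with a count of 0, and 12 probes passed under the limit on missing spots that was used first, at most 6 missing arrays per probe. Without slides 5 and 6, which left 2 arrays in each AgNO3 group, the differences were 0.75 (SE 0.30), 1.17 (SE 0.40) and 1.04 (SE 0.36) in the order given. With slide as a block 10 passed. The fit assumes 1 spread for all exposures, which is too small for the AgNO3 arrays, and these exposures lay on different slides scanned on different days.

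The remaining contrasts of particles with ions gave 0 calls with limma among 11951 probes. Between citrate 3.5 and AgNO3 0.32, DM11751P1 had effects of 0.19 and -1.01 (SE of the difference 0.31) and DM03178P2, well above background on 3 of 6 arrays in the AgNO3 control, effects of -0.33 and 0.73 (difference -1.06, SE 0.29). Between PVP 1.0 and AgNO3 0.08, DM04369P3 had effects of 3.40 and -1.67 (difference 5.07, SE 1.31) and DM01970P1 effects of -1.74 and 0.97 (difference -2.71, SE 0.60, adjusted p = 0.386). The low-dose nanoparticle and AgNO3 controls themselves differed, at 0.63 and 2.81 for DM04369P3 and at 6.27 and 4.68 for DM01970P1. PVP 1.0 stood at 4.52 for DM01970P1, near the AgNO3 control. Between citrate 0.43 and AgNO3 0.08, DM01517P2 had effects of 0.14 and -0.95 (SE of the difference 0.34) and DM00848P1 effects of 0.51 and 1.99 (difference -1.49, SE 0.46). At an unadjusted p under 0.05 there were 274, 263 and 341 probes in these 3 contrasts. The 95% interval of the difference excluded 2-fold for 45.1%, 45.6% and 43.6% of probes.

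The 3 unexposed control groups gave the background for comparisons across exposures. A moderated F test called 1805 of 11951 probes between them, of which 1066 were higher and 739 lower in the second than in the first control group. This split depended on scaling: with normexp and quantile normalization 561 were higher and 1179 lower, with median centring 737 and 1478, and 1590 and 48 with the deposited values. The first control group differed from the others in slide and scan day as well. The control groups of the low-dose and high-dose nanoparticle exposures shared slides, and in a comparison added later limma called 0 of 11921 probes between them without a block and 7 with slide as a block, with 1011 and 1519 at an unadjusted p under 0.05.

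Log2 fold changes against control were correlated across probes for the 21 pairs of comparisons; probes are not independent replicates. For the 5 pairs that share controls, Pearson's r ranged from 0.36 to 0.67. It was 0.67 between citrate 0.43 and PVP 1.0, where unchanged groups simulated against those controls gave a mean of 0.48 and a 95% range of -0.03 to 0.83. Its covariance was 0.049 against 0.041 simulated, and with the controls split 3 against 3 the mean r was -0.05. Between citrate 3.5 and PVP 8.1, r was 0.41 against a simulated 0.52, and it was -0.20 with split controls. For AgNO3, r was 0.38 between 0.08 and 0.16 µg/L, 0.39 between 0.08 and 0.32 µg/L and 0.36 between 0.16 and 0.32 µg/L, against simulated means of 0.48, 0.48 and 0.49. The observed covariances for AgNO3 were 0.053, 0.061 and 0.052 against simulated 0.112, 0.109 and 0.112, and split controls gave r of -0.31, -0.26 and -0.31. For the 16 pairs with no shared control, r ranged from -0.26 to 0.28. All 21 values lay inside the 95% range simulated for unchanged groups. These ranges were wide, so the simulation could exclude little. Simulated covariances also stayed above the observed ones for the AgNO3 pairs and for citrate 3.5 with PVP 8.1 (0.066 simulated, 0.031 observed). Overlap of called probes could not be computed, since no comparison with control had a call.

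**Figure D4:**
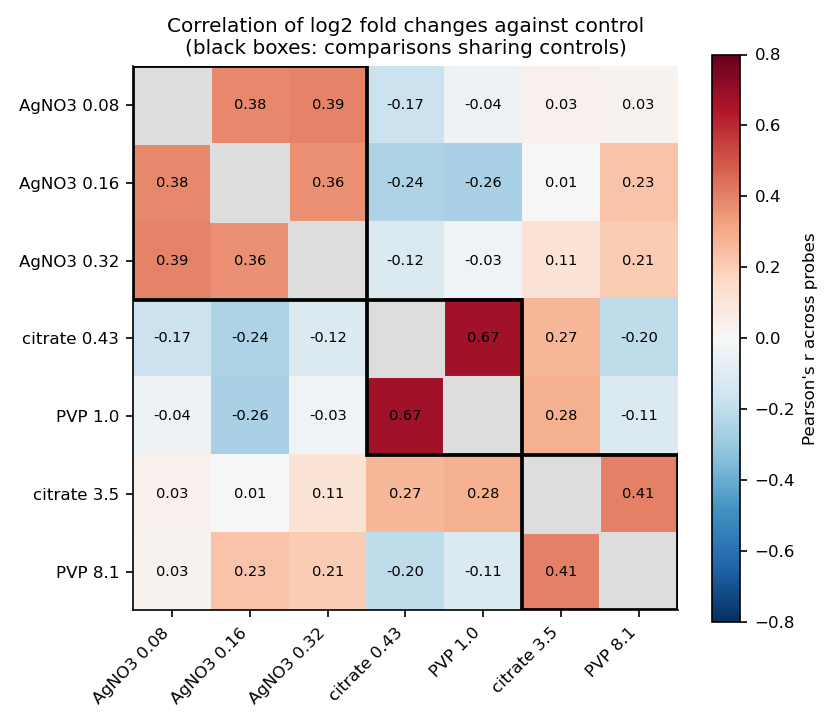
Pearson correlation across probes of the log2 fold changes against control for each pair of the 7 comparisons, with black boxes around comparisons that share controls. Within the boxes r lies between 0.36 and 0.67, and outside them between -0.26 and 0.28.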

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

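The tests in this part that leave out slides 3, 5 and 6, remove the spatial trend, use the first limit on missing spots, leave out single arrays or regroup arrays within slides were chosen only after the result was seen. Single arrays that stood apart from the other 5 of their group were looked for in 132 sets of 6 values by Dixon's criterion at the 95% level, which chance exceeds in about 1 in 20 sets. It was exceeded in 8.

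In the AgNO3 control group, DM03056P3 was at -4.13 on replicate 4, against -3.49 to -3.21 on the others, and DM01970P1 was at 6.04 on replicate 5, against 3.87 to 4.68. DM01266P2 was at -1.45 on AgNO3 0.08 replicate 2, against -0.63 to -0.36. DM00761P3 was at -2.89 on citrate 3.5 replicate 6, against -5.75 to -4.80, and without that array its difference from control was 0.63 in place of 1.03. DM08948P2 was at -0.43 on replicate 6 of the high-dose control group, against -1.04 to -0.92. DM01517P2 was at -1.67 on citrate 0.43 replicate 4, against -1.36 to -1.19. DM00848P1 was at -3.68 on PVP 8.1 replicate 4, against -2.44 to -1.97. In the low-dose control group, replicate 4 had 13463 spots well above background, against 11332 to 11967, and this array lay on slide 3, which was quantified with another protocol version.

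The effects of PVP 8.1 and AgNO3 0.32 differed for 3 probes in a test of the difference itself. Over probes with no missing spot 12 differed, and 2 of 100 regroupings of the arrays, the actual one included, gave as many, with 87 as the highest other. With slide as a block 10 differed over these probes, and 2 of 100 regroupings kept within slides gave as many, with 38 as the highest other. These shares are small, but this contrast was picked from many put through regroupings, with no correction for that, so chance is not firmly excluded. Regroupings with several times the actual count point to a structure of the samples. The spatial trend removed gave 18 probes, the first limit on missing spots gave 12, and leaving out slides 5 and 6 or slide 3 gave 0 with limma, with 325 and 333 at an unadjusted p under 0.05. For DM06365P2, DM04885P2 and DM00679P3 the differences were 1.42 (SE 0.26), 1.81 (SE 0.34) and 1.22 (SE 0.25) with all slides. Without slide 3, which left 4 arrays of PVP 8.1 and 5 of its control, they were 1.45 (SE 0.30), 1.71 (SE 0.38) and 1.28 (SE 0.27), so sizes moved little while errors grew. Without slides 5 and 6, which left 2 of 6 arrays in each AgNO3 group, they were 0.75 (SE 0.30), 1.17 (SE 0.40) and 1.04 (SE 0.36), and fewer arrays and the slides themselves were not separated. Exposure, slide and scan day cannot be told apart here.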

How the results depend on the processing

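Removal of the spatial trend, fits within or without single slides, the first limit on missing spots, array scores as covariates and single arrays left out are tests chosen only after the result was seen. For PVP 8.1 against control, limma called 0 probes in the setting reported, with 989 at an unadjusted p under 0.05. It called 17 with normexp and quantile normalization, 6 with median centring, 5 with the deposited value table, 26 with no filter, 15 over probes well above background on every array, 1 with the replicate block, 5 with array weights, 1 with all 60 arrays in one fit, 10 with the spatial trend removed and 97 with array scores as covariates. For the effect of PVP 8.1 against that of AgNO3 0.32, where 3 were called, the counts were 5 with normexp, 0 with the deposited table, 18 on every array, 9 with the replicate block, 10 with the slide block, 0 with array weights, 18 with the spatial trend removed, 0 without slides 5 and 6, 0 without slide 3, 12 with at most 6 missing arrays per probe and 24 with array scores. For the effect of PVP dose, 2 were called with the replicate block and 20 with array weights. For citrate 3.5 against PVP 8.1, 4 were called with array weights, 1 with the spatial trend removed and 2 with array scores. For AgNO3 0.08, 1 was called with all 60 arrays and 4 within slide 5, and for AgNO3 0.32, 21 with all 60 arrays and 2, DM10695P1 and DM11131P3, with the spatial trend removed. For the control groups, 1805 were called, 836 on every array and 2861 with array weights. The cause was not tested. Of the other counts, 195 stayed within 1.5 times the reported one. Most of these were 0 in both settings, which says little about stability. Of the named probes' values, 601 kept direction and side of the threshold, 41 passed it newly, 13 no longer passed it, and none reversed. All 42 correlations recomputed moved by less than their simulated spread.

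Same-numbered replicates were checked for pairing. In the 3 exposures, 25 of 36, 13 of 18 and 12 of 18 pairs correlated above 0.1, and an array correlated best with its own number in 23 of 72, 13 of 36 and 16 of 36 cases, where chance gives 12, 6 and 6. Not every pair was above 0.1, so the numbers were not taken as pairs, but the excess over chance is a hint from the data that they carry a shared factor. In the AgNO3 exposure the number goes with slide and slide column. In the nanoparticle exposures most same-numbered arrays also lay on the same slide, so number and slide are largely not separated there either. The replicate block called 1 probe for PVP 8.1, 2 for PVP dose and 9 for PVP 8.1 against AgNO3 0.32, and no other count at the adjusted threshold moved with it. At an unadjusted p under 0.05 its counts were higher in 16 of 16 comparisons and by over 1.5 times in 12. They went from 194 to 408 for citrate 0.43, 363 to 759 for PVP 1.0, 290 to 576 for citrate 3.5, 989 to 1520 for PVP 8.1, 176 to 471 and 302 to 492 between coatings, 116 to 239 and 333 to 527 for citrate and PVP dose, and from 341, 263, 274 and 436 to 531, 424, 478 and 672 for citrate 0.43, PVP 1.0, citrate 3.5 and PVP 8.1 against AgNO3. The slide block moved 4 by over 1.5 times: to 437 for citrate 0.43, 479 between high-dose coatings, 210 for citrate dose and 516 for citrate 0.43 against AgNO3. The test over all 3 control groups could not be fitted with the slide block, since the first lies on slides of its own, nor with the replicate block, whose numbers were taken within an exposure. The deposited table moved the median log2 change over probes to 0.17 for PVP 8.1 (from -0.06), 0.10 for citrate 3.5, 0.12 for PVP dose and 0.24 between the first 2 control groups, and median centring moved the contrasts with AgNO3 0.08 to -0.11. Dim probes limit what can be read: 9570 to 13736 of 15208 spots were well above background.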

Other observations

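The pooled tests, the array scores, the tests of slide for both scores, the regroupings within slides, the directions of the called probes in other comparisons and the spatial test in this part were chosen only after the result was seen. The number of scores was also set after counts were seen, and the spatial test reported replaced an earlier one, removal of each array's spatial trend, which left the ratio of spreads at 1.43.

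When the 7 exposed groups were each set against their control and averaged, 3 of 11951 probes passed the adjusted threshold with limma, with 505 at an unadjusted p under 0.05. DM00355P1 averaged -0.64 (SE 0.12, adjusted p = 0.0253), DM14325P3 -0.52 (adjusted p = 0.0324) and DM14887P2 -0.40 (adjusted p = 0.038), each lower in 7 of 7 groups. Over probes with no missing spot, 6 of 100 regroupings, the actual one included, gave 3 or more, with 36 as the highest other, so chance is not excluded. For the 3 AgNO3 groups, 1 of 11951 probes passed, DM00848P1 at 1.43 (adjusted p = 0.0236). By inspection its sequence resembles bacterial ribosomal RNA, which was not tested, so that its organism stays open. Over probes with no missing spot 2 passed, and 52 of 100 regroupings gave as many, with a highest of 1066. For the 4 nanoparticle groups limma called 0, with 257 at an unadjusted p under 0.05, and 100 of 100 regroupings gave as many, with a highest of 157.

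For the single comparisons with a count of 0 at the adjusted threshold, all 100 of 100 regroupings reach it, so these say nothing about chance. The highest other counts were 1 for AgNO3 0.08, 0 for AgNO3 0.16, 347 for AgNO3 0.32, 342 for citrate 0.43, 33 for PVP 1.0 and 0 for both high-dose coatings. They were 119 and 40 between coatings, 1 between AgNO3 doses, 2 and 12 for citrate and PVP dose, and 27, 19 and 562 for the contrasts of citrate 0.43, PVP 1.0 and citrate 3.5 with AgNO3. At an unadjusted p under 0.05, the actual counts in the order of the 7 comparisons were 163, 147, 460, 193, 361, 290 and 989. They were reached by 86, 84, 32, 76, 65, 52 and 14 of 100 regroupings, with highest others of 1310, 1529, 2040, 3021, 2113, 3228 and 2487, so chance is excluded for none of them by regroupings that did not keep slides balanced. With regroupings kept within slides and slide as a block, the actual counts were 215, 198, 571, 434, 491, 401 and 1263. As many were reached by 75, 70 and 22 of 100 regroupings for AgNO3, 32 of 72 for citrate 0.43, 44 of 54 for PVP 1.0, 23 of 72 for citrate 3.5 and 7 of 72 for PVP 8.1. The highest others were 1814, 1223, 1062, 1837, 2095, 1341 and 1841, so chance is not excluded by these either. Regroupings that call many probes point to a structure of the samples that the groups do not explain. Between the control groups, 1754 probes passed over probes with no missing spot, 1 of 100 regroupings gave as many and the highest other was 398.

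Arrays of the AgNO3 exposure scattered more: the mean of the groups' median SDs was 0.492, against 0.349 in the low-dose nanoparticle exposure, a ratio of 1.41. Over the middle 60% of rows, outside the dim and bright edges, the ratio was 1.26 (1.13 to 1.52 over pairs of groups), and among the probes with the highest mean signal 1.38, so neither a spatial defect nor lower brightness was excluded or singled out. A cause in the animals or the RNA was not tested.

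Within groups, arrays of the nanoparticle exposures varied together. The first 2 components held 50.6% and 55.0% of the within-group variance in the low-dose and high-dose exposures, and 38.2% in the AgNO3 exposure. The scores tested here are not these components. Each nanoparticle exposure was scored on 2 components of the other, and AgNO3 on 2 components of both. The scored components captured 28.5% and 31.3% in the low-dose and high-dose exposures and 18.6% in AgNO3. If an exposure's within-group variance were spread evenly over its own components, 2 of them would hold 13.3%, 13.3% and 10%. These values are no chance level for components taken from another exposure. Slide as the whole cause of the first score is argued against, since 0.817 of its variance lay between arrays of one slide (0.719 and 0.891 in the single exposures), where shuffled slides gave a median of 0.75 and a 95% range of 0.519 to 0.923. For the second score that share was 0.616, with 0.494 and 0.704 in the single exposures. Shuffled slides gave a median of 0.747 and a 95% range of 0.511 to 0.899, which holds 0.616. No slide effect was therefore shown for the second score, and slide stays open for it. Array brightness as the cause of the first score is argued against too: its Spearman correlation with that score was 0.169 (permutation p = 0.324) and Pearson's r 0.106 (permutation p = 0.539; 0.188 without the 2 farthest of 36 arrays). Brightness was not tested for the second score. The scores did not pass an exact test between any exposed group and control, with a lowest adjusted p of 0.985 over 14 tests. Differences between pools of animals, such as in moult or reproductive stage, may contribute and were not tested.

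With 2 such scores, built from the low-dose nanoparticle exposure, as covariates, 97 probes passed between PVP 8.1 and control. Of these, 57 were higher and 40 lower, all 97 in the same direction without the scores. Over these 97 probes the median size was 0.68 with and 0.69 without scores, and the median residual SD 0.225 and 0.301. They were chosen for passing with the scores, so their smaller residual SD is no separate support. With 1 score 37 passed and with 3 scores 193. Over probes with no missing spot 100 passed, 1 of 100 regroupings gave as many and the highest other was 0. Of 72 regroupings kept within slides, 1 gave as many, again with 0 as the highest other. Without slide 3 the median ratio of fold changes was 1.05 (quartiles 0.987 to 1.11). The probes had been chosen by low p on all arrays, slide 3 included, which favours a ratio near 1. The ratio therefore does not decide whether slide 3 was the source. On the 9 arrays left in these groups 0 probes passed with limma, with 1818 at an unadjusted p under 0.05. A response to PVP 8.1 hidden by that variation is a hypothesis found and tested on the same data.

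The 97 probes were not shown to be particular to PVP 8.1. With citrate 3.5, set against the same control arrays, 94 of the 97 went the same way, where unchanged groups simulated against shared controls gave a mean of 81.2 and a 95% range of 55.8 to 95.5. With the controls split 3 against 3 the mean was 89.4, although the probes had been chosen with all control arrays. The median ratio of the citrate 3.5 to the PVP 8.1 effect was 0.38 (quartiles 0.23 to 0.54). With controls of their own, 69 of 97 went the same way in PVP 1.0 and 31 of 97 in citrate 0.43, and in AgNO3 0.08, 0.16 and 0.32 the counts were 37, 73 and 42 of 92. These values do not separate a response to PVP 8.1 from one shared with citrate 3.5 or from a deviation of the control group itself.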
